A study of Homo sapiens with 6 samples.

How the data were processed

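RNA from 6 samples of the breast cancer cell line BT549 was sequenced, 3 carrying a control vector and 3 a GATA3 overexpression vector, as the sample titles and genotype labels give them. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from total RNA with an Illumina TruSeq RNA kit. How RNA was selected and whether strand was kept are not given in the sources used here. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used. Their versions and settings, the genome build and the gene annotation are not given in the sources used here. The labels conflict in 2 places. The series title speaks of suppression of GATA3 while the design text and genotype labels speak of overexpression, and the growth notes name the cell line HCC1806 while the titles and the cell line label name BT549. Groups were taken from the titles and genotype labels.

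The authors deposited a table of TPM values (length-normalized transcript abundance), given to 2 decimals, for 60879 genes in each of the 6 libraries, per the file headers. TPM divides reads by gene length and scales each library to a fixed total, so a gene's value also depends on all other genes. It keeps no record of read number, so the depth of each library is unknown and no counting interval can be given. Each deposited group mean lay within 3.33e-05 TPM of the mean of the 3 libraries. Of the gene IDs, 58396 are in GENCODE release 29 for GRCh38, the annotation that gave coordinates, gene types and GC content here. A further 215 entries are StringTie's own gene models, and 40609 entries carry a symbol. No pair of libraries held identical values. Because strand is not stated, values of overlapping and antisense genes are uncertain. So are those of near-identical copies, among them ANXA8 and ANXA8L1, HSPA1A and HSPA1B, the HLA genes, the IFITM genes, ribosomal protein genes and the multicopy 5S RNA entry RNA5S17. The symbol RGS5 stands on 2 IDs, and the protein-coding ENSG00000143248 is the one reported.

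Values were analysed as log2(TPM + 1), a pseudocount of 1 TPM, for the 14077 genes with at least 1 TPM in at least 3 of 6 libraries. Fold changes are differences of group means on this scale, GATA3 minus control, and understate changes of genes with low values. Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values were read with data.table version 1.17.8 and statmod 1.5.0 was used for array weights. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Means are given ± SD with n = 3. A gene listed at 0 throughout 1 group is given without a fold.

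The groups, tests, gene lists, cell type markers, alternatives and the rule for named genes were fixed before the data were examined. An exception among the alternatives, shares of summed TPM over protein-coding genes alone, was added after the data were seen. Named genes are GATA3, the 12 rising and 12 falling genes with the largest change among called genes whose groups do not overlap, up to 4 called members of each list or printed term with the lowest p, and all members of the luminal, junction and GATA family lists. Members beyond this rule that make up a small count, as well as COL4A2, VIM, KRT5, STAT2, TAPBP and ERAP1, were named after their values were seen. So were the counts of cytosolic and mitochondrial ribosomal protein genes. A few genes that the rule would name are not reported here. Lists covered luminal, basal, epithelial junction, mesenchymal, collagen and basement membrane, matrix protease, integrin, TGF-beta, YAP, G1/S, G2/M, cyclin D and cell cycle inhibitor, homologous recombination, p53, interferon-stimulated, antigen presentation, NF-kappaB, hypoxia, cholesterol, fatty acid, oxidative phosphorylation, endoplasmic reticulum stress, Notch, Wnt, tumour-initiating, angiogenic, GATA3-responsive, GATA family, T helper 2, immediate early, heat shock and mitochondrially encoded genes. Marker lists covered immune, endothelial, erythroid, fibroblast and epithelial cells. Lists with at least 5 tested members were tested against the other genes with limma's camera at a preset correlation of 0.01 and adjusted over the 31 lists. Terms that the authors' table carries for Gene Ontology and KEGG, with 10 to 500 tested genes, were tested with Fisher's exact test in each direction against tested genes with a term of that kind, and adjusted over 3804 tests. Shares of summed TPM and GATA3 were compared with exact two-sided permutation tests of 3 against 3 libraries, which cannot go below p = 0.1.

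Alternatives covered the pseudocount, the filter, the scaling of libraries, the limma settings, a test against a 1.2-fold change, the replicate number as a block, protein-coding genes only, a threshold of 0.01, other list tests and leaving out each library. All 10 splits of the 6 libraries into 3 and 3 were also run. The test was run on simulated data for 14077 genes of which 200 were changed. It recovered 70.1% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 93.9% of those changed 4-fold, with 10 false calls among 174. It also recovered the 1 list of 32 that was shifted and called no other. Simulated genes varied independently and the lists were random genes, so false list calls from correlated members could not arise. With 200 changed genes, against 5155 called in the data, its rates do not carry over directly.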

Results

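RNA from BT549 cells, a human breast cancer line with a mesenchymal appearance, was sequenced in 6 libraries. Of these, 3 libraries came from cells carrying a control vector and 3 from cells carrying a GATA3 vector, and the 2 groups are called control and GATA3 cells here. GATA3 is a zinc finger transcription factor of the luminal lineage of the mammary gland. The comparison asks which transcripts differ between GATA3 and control cells. Between 13834 and 14097 genes reached 1 TPM in a library. The depth of each library is unknown, because TPM keeps no record of read number.

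GATA3 itself (ENSG00000107485, chromosome 10, positions 8045378 to 8075203 in GRCh38) was listed at 43.68, 42.00 and 42.62 TPM in the control libraries and at 90.80, 98.98 and 87.00 TPM in the GATA3 libraries. The means were 42.8 ± 0.850 and 92.3 ± 6.12 TPM (SD, n = 3 each), a 2.16-fold difference. On the log2(TPM + 1) scale GATA3 rose by 1.09 (SE 0.05, limma adjusted p = 1.09e-05). An exact two-sided permutation test of the same difference gave p = 0.1, the smallest value that 3 against 3 libraries allow. GATA3 was thus higher in all 3 libraries labelled as overexpressing it, whereas the series title speaks of suppression.

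**Figure D1:**
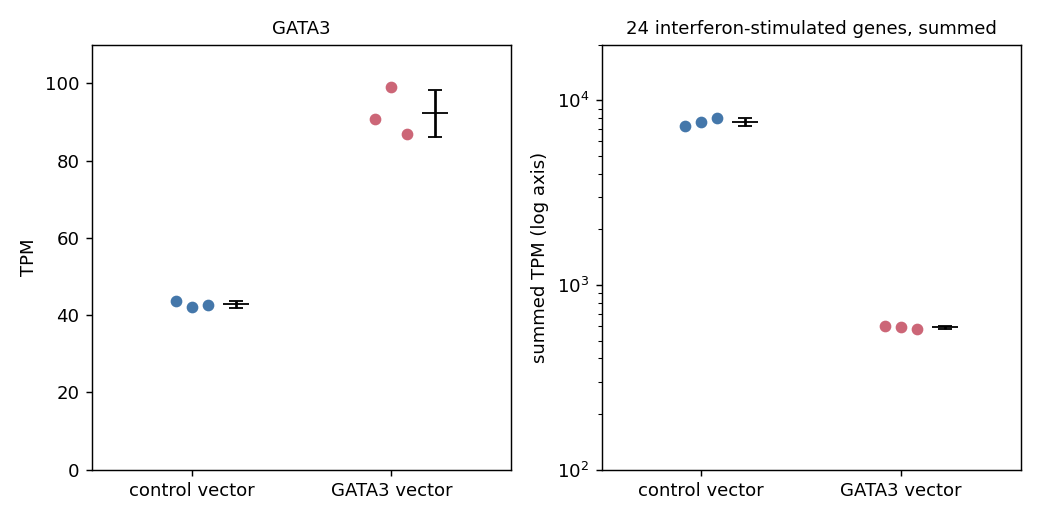
GATA3 in TPM on a linear axis from 0 (left) and the summed TPM of 24 interferon-stimulated genes on a log axis (right) in control and GATA3 cells; points are libraries and the black marks are mean ± SD (n = 3). GATA3 lay at 42.8 and 92.3 TPM, and the summed interferon-stimulated genes at 7648 and 590.2 TPM.

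Among genes that fell in GATA3 cells were many interferon-stimulated transcripts. IFI27, a mitochondrial protein gene induced by interferon, fell from 860.0 ± 94.3 to 8.14 ± 1.77 TPM (log2 fold change −6.57, SE 0.14, adjusted p = 2.75e-07, n = 3). The antiviral membrane protein genes IFITM1 and BST2 fell from 888 ± 20.2 to 11.7 ± 3.26 TPM and from 509.5 ± 30.9 to 6.99 ± 0.858 TPM, a log2 fold change of −6.16 for IFITM1. MX1, a GTPase that blocks viral replication, fell from 282 ± 12.3 to 5.70 ± 0.294 TPM (−5.40). IFI6, IFI44L, OAS1, OAS2 and XAF1 fell with log2 fold changes between −5.26 and −4.57. Outside the interferon response, IL13RA2, a decoy receptor for interleukin 13, fell from 53.1 ± 2.66 to 0.317 ± 0.178 TPM (−5.37, and −7.08 with a pseudocount of 0.1 TPM, beyond the −6.72 of IFI27 there), and TH, the rate-limiting enzyme of catecholamine synthesis, fell from 69.0 ± 1.87 to 2.63 ± 0.331 TPM (−4.27). The 5S ribosomal RNA entry RNA5S17 was at 44.46, 14.84 and 19.55 TPM in the control libraries and was listed at 0 in each GATA3 library.

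Among rising genes, OLFML3, which encodes a secreted glycoprotein, rose from 0.660 ± 0.320 to 49.4 ± 0.808 TPM (log2 fold change 4.94, SE 0.14, adjusted p = 9.82e-07). TAGLN, an actin-binding protein of smooth muscle, rose from 11.4 ± 2.82 to 182 ± 19.2 TPM (3.90). HAND1, a basic helix-loop-helix transcription factor, rose from 11.8 ± 0.741 to 112 ± 4.35 TPM (3.15), and RGS5, a regulator of G protein signalling, rose from 30.6 ± 1.97 to 225 ± 10.9 TPM (2.84). The annexin genes ANXA8 and ANXA8L1, which are near-identical copies, rose by 3.70 and 3.47. NSG1, DACT1, C4BPB, NPY and MGAM rose by 2.90 to 3.80, from control means of at most 2.06 TPM. CRYAB, a small heat shock protein gene, was listed at 0 in all 3 control libraries and at 19.36, 15.22 and 19.37 TPM in the GATA3 libraries.

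**Figure D2:**
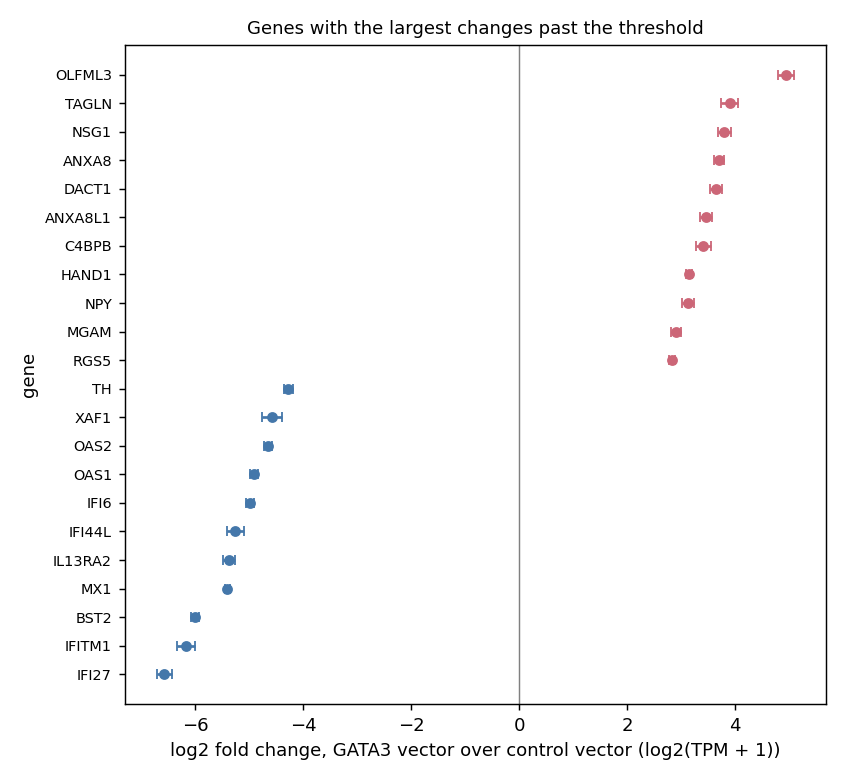
Log2 fold change (GATA3 over control cells, log2(TPM + 1) scale) of the named genes with the largest changes; points are limma estimates and bars are 1 SE (n = 3 per group), red for higher and blue for lower in GATA3 cells. OLFML3 lies highest at 4.94 and IFI27 lowest at −6.57; CRYAB and RNA5S17, listed at 0 throughout 1 group, are left out.

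In all, 5155 of 14077 tested genes (36.6%) differed at an adjusted p below 0.05, of which 1988 were higher and 3167 (61.4%) lower in GATA3 cells. The share of lower genes fell to 50.7% (2476 higher, 2550 lower) when libraries were scaled by median ratios and to 47.4% (2612 higher, 2350 lower) after quantile normalization. Most changes were small: 3112 of the 5155 genes (60.4%) changed by less than 0.5 on the log2 scale, and the median size was 0.41. At least 2-fold changes were found for 689 genes, 240 higher and 449 lower. Log2 values correlated across genes with r of 0.986 to 0.987 within groups and 0.959 to 0.961 between them, and the first principal component held 64.0% of the variance, with genes not being independent replicates.

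All 24 members of the interferon-stimulated list fell in GATA3 cells, with log2 fold changes from −6.57 for IFI27 to −1.02 for STAT2. ISG15, a ubiquitin-like modifier, fell from 1756 ± 81.8 to 185 ± 4.23 TPM (−3.24). Summed over the list, transcripts dropped from 7648 ± 354 to 590.2 ± 10.2 TPM, so that control cells held 13.0 times as much. The list median was −3.12 and its camera adjusted p was 7.63e-25 against the other genes (adjusted p = 0.0385 with an estimated correlation). Adjusted over the list alone, the same count of 24 members was lower.

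Antigen presentation genes fell alongside: 15 of 17 tested members were lower and none higher, with TAPBP (−0.02) and ERAP1 (−0.12) not passing. HLA-B and HLA-C, heavy chains of major histocompatibility class I, fell from 787 ± 34.4 to 273 ± 7.66 TPM (−1.52) and from 935 ± 10.7 to 492 ± 6.90 TPM (−0.92), and their partner B2M fell from 1979 ± 45.8 to 1178 ± 34.1 TPM (−0.75). The list median was −0.74 and the camera adjusted p 8.43e-08 (adjusted p = 0.306 with an estimated correlation), and 15 members were lower adjusted over the list alone. Of the 19 tested NF-kappaB and inflammatory cytokine genes, 10 fell and 4 rose (11 and 5 adjusted over the list alone). The cytokine genes IL6 and IL1B fell by 1.74 and 1.64 on the log2 scale, while the chemokine gene CCL2 rose from 16.0 ± 2.16 to 71.9 ± 4.57 TPM (2.11). That list as a whole did not pass (median −0.40, camera adjusted p = 0.346).

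**Figure D3:**
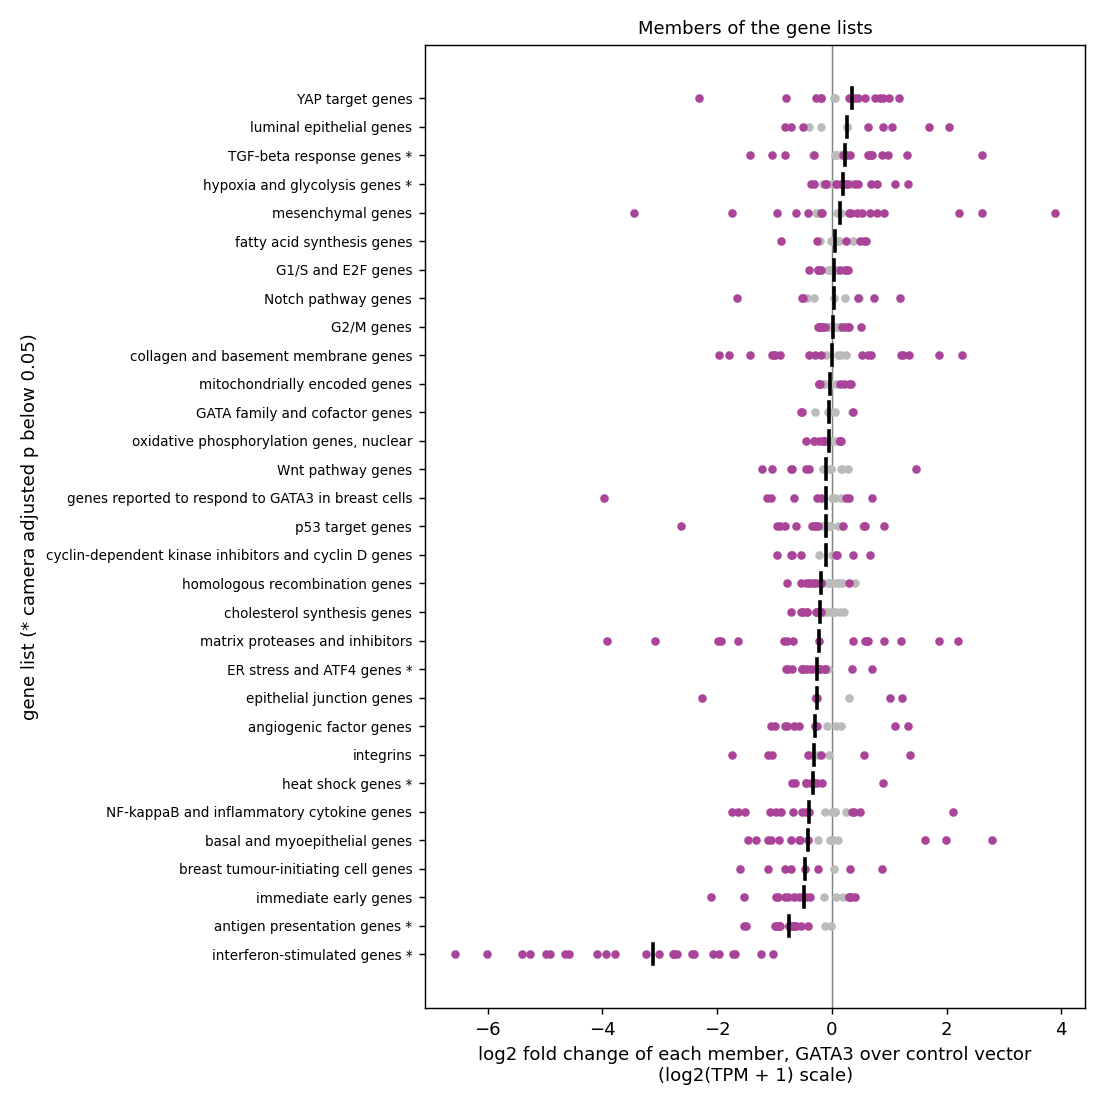
Log2 fold change (GATA3 over control cells) of each tested member of 31 gene lists, purple where the member passed an adjusted p of 0.05 and grey where it did not; the black mark is the list median and an asterisk marks a camera adjusted p below 0.05. The interferon-stimulated genes lie farthest from 0, with a median of −3.12.

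Luminal genes moved in both directions. KRT8, a keratin of simple epithelium, and its filament partner KRT18 rose from 24.8 ± 1.99 to 105 ± 4.03 TPM (2.04) and from 793 ± 25.5 to 2568 ± 34.7 TPM (1.70), and the carbonic anhydrase gene CA12 rose by 1.04. ERBB2 and MUC1 rose by 0.63 and 0.88, while MLPH and PRLR were among those that fell, by 0.82 and 0.51 on the log2 scale. KRT7 (−0.39), XBP1 (−0.20), TBC1D9 (0.27) and ERBB3 (0.26) did not pass. FOXA1, ESR1 and PGR, transcription factors of the hormone-responsive luminal state, had means of at most 0.153 TPM in either group. Of the 12 tested luminal genes 5 rose and 3 fell (5 and 5 adjusted over the list alone), with a median of 0.26 and a camera adjusted p of 0.166. The call for MUC1 was lost without control replicate 1 (adjusted p = 0.0595), control replicate 2 (0.0581), GATA3 replicate 1 (0.0695) or GATA3 replicate 2 (0.0652), and without the filter on low values (0.0789), within a range of 0.0146 to 0.124 over the settings run. KRT7 passed without control replicate 1 (adjusted p = 0.0184, range 0.0184 to 0.803). XBP1 passed without control replicate 1 (adjusted p = 0.0370) and, narrowly, among protein-coding genes alone, within a range of 0.0370 to 1. TBC1D9 passed after quantile normalization (adjusted p = 0.0493) and without an intensity trend (0.0366), within a range of 0.0366 to 1.

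Among 17 tested basal and myoepithelial genes, 9 fell and 3 rose, and the counts adjusted over the list alone were the same. The 3 that rose were ACTA2, smooth muscle actin, from 37.9 ± 0.892 to 269.5 ± 11.1 TPM (2.80), the oxytocin receptor gene OXTR (2.00) and KRT14 (1.62). The laminin-binding integrin gene ITGA6 fell by 1.11 and KRT5 by 0.91. The list median was −0.42, the mean −0.11 and the camera adjusted p 0.448, with a camera statistic pointing downward and fry's directional test upward (adjusted p = 0.000509). The mean turned to 0.16 among genes with a mean of at least 5 TPM and to 0.04 with a pseudocount of 5 TPM. Only 7 of the 23 epithelial junction genes could be tested, and CDH1, which encodes E-cadherin, averaged 0.190 TPM in control and 1.02 TPM in GATA3 cells. JUP and OCLN, components of desmosomes and tight junctions, rose by 1.22 and 1.02, while DSP, CLDN1 and PKP3 fell by 2.26, 0.25 and 0.28, and TJP1 (0.31) and CGN (−0.29) did not pass. Adjusted over the list alone, 3 were higher and 4 lower. The junction median was −0.25 and the mean −0.08, while the camera statistic pointed upward (adjusted p = 0.955) and the mean turned to 0.00 after quantile normalization or with a pseudocount of 5 TPM. PKP3 lost its call without control replicate 1 (adjusted p = 0.107), control replicate 3 (0.102), GATA3 replicate 2 (0.105) or GATA3 replicate 3 (0.103). It also lost it with median ratio scaling (adjusted p = 0.0704), after quantile normalization (0.0950) and without the filter on low values (0.0765), within a range of 0.0297 to 1 over the settings run. TJP1 passed after quantile normalization (adjusted p = 0.0400) and without control replicate 2 (0.0417), within a range of 0.0133 to 1, and CGN passed without an intensity trend (adjusted p = 0.0174, range 0.0174 to 1).

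Mesenchymal and matrix genes moved in both directions. TGFBI, a secreted adhesion protein induced by TGF-beta, rose from 64.4 ± 2.52 to 404 ± 33.8 TPM (2.63), while TNC, the matrix glycoprotein tenascin C, fell from 39.1 ± 2.53 to 2.68 ± 0.313 TPM (−3.45). Of 22 tested mesenchymal genes 10 rose and 7 fell, with equal counts adjusted over the list alone (median 0.14, camera adjusted p = 0.154). VIM, the vimentin gene, fell from 4522 ± 48.1 to 4021 ± 54.2 TPM (−0.17). Among 22 collagen and basement membrane genes 8 rose and 10 fell, also adjusted over the list alone. HSPG2, which encodes perlecan, rose by 2.26 and COL6A2 by 1.24, whereas COL4A2, a basement membrane collagen chain, fell by 1.97 and LAMB1 by 1.01. That list had a median of −0.00, a mean of 0.01 and a camera statistic pointing upward (adjusted p = 0.355), and the mean turned to −0.01 without GATA3 replicate 1, −0.02 without the filter on low values and −0.09 with a pseudocount of 0.1 TPM. All 17 tested matrix proteases and inhibitors changed, 8 up and 9 down, again also adjusted over the list alone (median −0.23, camera adjusted p = 0.845). MMP3, the protease stromelysin, fell from 71.5 ± 1.67 to 3.80 ± 0.512 TPM (−3.92), the lysosomal protease gene CTSL fell from 1942 ± 36.8 to 489.7 ± 22.8 TPM (−1.99) and the urokinase gene PLAU fell by 1.93. Of 10 tested integrins, 5 fell, led by the fibronectin receptor subunit ITGA5 (−1.73), and ITGA2 (1.37) and ITGAV (0.56) rose. Integrin counts were the same adjusted over the list alone, with a median of −0.31 and a camera adjusted p of 0.159.

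Genes of the TGF-beta response were higher as a list: 11 of 22 rose and 4 fell (12 and 5 adjusted over the list alone), with a median of 0.23 and a camera adjusted p of 0.00153 (adjusted p = 0.306 with an estimated correlation). ID2, an inhibitor of helix-loop-helix factors, rose from 239.95 ± 15.4 to 472 ± 15.9 TPM (0.98) and the TGF-beta binding protein gene LTBP3 rose by 0.68. The 4 that fell were the receptor gene TGFBR2 (−1.04), LTBP1 (−1.43), BMP2 (−0.81) and BMP4 (−0.31). Of 16 tested YAP targets, 9 rose and 5 fell, as adjusted over the list alone. ARHGEF17, AJUBA and CCN1 rose by 1.18, 0.89 and 0.75, while NT5E, the ecto-enzyme CD73, fell from 283 ± 1.15 to 56.1 ± 0.469 TPM (−2.32). The YAP list had a median of 0.35 and a camera adjusted p of 0.0605, which became 0.0428 without GATA3 replicate 1 and 0.0450 without GATA3 replicate 3 (range 0.0428 to 0.361 over the settings run).

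Cell cycle lists had medians near 0. Of 22 tested G1/S genes 4 rose and 4 fell, also adjusted over the list alone, with RRM2, a subunit of ribonucleotide reductase, at −0.39 and TYMS, thymidylate synthase, at 0.22 (median 0.05, camera adjusted p = 0.321). Of 24 G2/M genes 5 rose and 6 fell (6 and 6 adjusted over the list alone), with the kinesin gene KIF20A at 0.50, the topoisomerase gene TOP2A at 0.30 and CDC20 at −0.19 (median 0.02, camera adjusted p = 0.302). The cyclin genes CCND1 and CCND3 fell by 0.71 and 0.54 on the log2 scale, and so did the cell cycle inhibitor genes CDKN1A (−0.96) and CDKN2D (−0.69). CDKN2B, CDKN1B, CDK4 and CDKN2A rose by 0.66, 0.37, 0.10 and 0.07. That made 4 higher and 4 lower of 10 tested inhibitor and cyclin D genes (4 and 5 adjusted over the list alone), with a median of −0.11 and a camera adjusted p of 0.631. Among 21 homologous recombination genes 8 fell, among them the damage kinase gene ATR (−0.53), and FANCI rose (0.29). Adjusted over the list alone 10 were lower and 1 higher (median −0.19, camera adjusted p = 0.355). Of 22 p53 targets 9 fell and 4 rose (9 and 5 adjusted over the list alone). GDF15, a stress-induced cytokine, fell from 26.0 ± 2.93 to 3.41 ± 0.711 TPM (−2.62), and AEN fell by 0.81 (list median −0.10, camera adjusted p = 0.448).

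Stress response genes were mostly lower. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 642 ± 6.79 to 369 ± 1.14 TPM (−0.80), and the stress transcription factor gene DDIT3 fell by 0.76. Of 20 endoplasmic reticulum stress and ATF4 genes 13 fell, while PHGDH (0.36) and SLC7A11 (0.70) rose. The counts were 14 lower and 2 higher adjusted over the list alone, with a median of −0.25 and a camera adjusted p of 0.00153 (adjusted p = 0.306 with an estimated correlation). Among 13 heat shock genes 12 fell, including the cytosolic chaperone gene HSPA8 (−0.32), HSPD1 (−0.45) and the cochaperone gene BAG3 (−0.64), and only HSPB1 rose, from 962 ± 13.2 to 1781 ± 51.4 TPM (0.89). Adjusted over the list alone the counts were unaltered, with a median of −0.33 and a camera adjusted p of 0.000140 (adjusted p = 0.361 with an estimated correlation). Of 18 immediate early genes 11 fell and 4 rose, as they did adjusted over the list alone. FOSL1, a subunit of AP-1, fell from 309 ± 5.50 to 106 ± 7.90 TPM (−1.54) and the ERK phosphatase gene DUSP6 fell from 28.2 ± 1.17 to 5.77 ± 0.384 TPM (−2.11). The immediate early median was −0.48 and the camera adjusted p 0.0605, which became 0.0424 without control replicate 2 (range 0.00805 to 0.361 over the settings run). After quantile normalization it was 0.0351 and with median ratio scaling 0.0373.

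Metabolic lists had medians between −0.20 and 0.20. Of 23 hypoxia and glycolysis genes 12 rose and 4 fell (13 and 5 adjusted over the list alone), with the oxygen-sensing hydroxylase gene EGLN3 at 1.33, the peptide hormone gene ADM at 0.68 and LDHA, lactate dehydrogenase, at 0.22. HK2, PFKFB3, GAPDH and PFKP, enzymes of glycolysis or its control, fell by 0.36, 0.30, 0.12 and 0.10. The hypoxia median was 0.20 and the camera adjusted p 0.0104 (adjusted p = 0.361 with an estimated correlation), and the call was lost without GATA3 replicate 2 (adjusted p = 0.0828). It was also lost after quantile normalization (adjusted p = 0.0665) and among genes with a mean of at least 5 TPM (adjusted p = 0.0727), within a range of 0.00184 to 0.361 over the settings run. Of 20 tested cholesterol synthesis genes 10 fell and none rose (11 and 2 adjusted over the list alone). HMGCS1, an early enzyme of the pathway, fell by 0.49 and INSIG1, a regulator of sterol sensing, fell by 0.44. The cholesterol median was −0.20 and the camera adjusted p 0.0605, which became 0.0133 without control replicate 2 and 0.0428 without GATA3 replicate 1 (range 0.00869 to 0.573 over the settings run).

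Of 15 fatty acid synthesis genes FADS2, DGAT2, SCD and SREBF1 rose by 0.60, 0.57, 0.49 and 0.24, while ELOVL6 and ACSL3 fell by 0.88 and 0.25. Adjusted over the list alone 5 were higher and 3 lower (median 0.06, camera adjusted p = 0.121). The ACSL3 call was lost without control replicate 1 (adjusted p = 0.0518) or GATA3 replicate 2 (0.0528) and after quantile normalization (0.0658), within a range of 0.0118 to 1 over the settings run. Nuclear genes of oxidative phosphorylation held 4 higher and 7 lower among 24 (5 and 9 adjusted over the list alone), with cytochrome c, CYCS, at −0.45 (median −0.06, camera adjusted p = 0.462). The 13 mitochondrially encoded genes held 4 higher and 3 lower, also adjusted over the list alone, with MT-CO3 at 0.29 and MT-ND1 at −0.23. Their median was −0.04, their mean 0.00 and the camera statistic pointed upward (adjusted p = 0.631). The mean became −0.06 after quantile normalization, −0.00 and −0.02 without control replicate 2 or 3, and −0.01 without GATA3 replicate 2 or 3.

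Among Notch genes 3 rose and 3 fell. DLL1, a Notch ligand gene, rose by 1.19, as did NOTCH3 (0.74) and LFNG (0.45), while the ligand gene JAG1 fell by 1.65 and NOTCH1 and HES1 by 0.53 and 0.51. With 11 genes tested (4 and 4 adjusted over the list alone), the Notch median was 0.04, the mean −0.03 and the camera statistic pointed upward (adjusted p = 0.631). The mean turned to 0.01 with median ratio scaling, 0.06 after quantile normalization, 0.04 among genes with a mean of at least 5 TPM, and 0.15, 0.14 and 0.12 without control replicate 1, 2 or 3. Of 14 tested Wnt genes 6 fell, including the secreted antagonist gene SFRP1 (−1.22) and MYC (−0.46), and DKK3 rose (1.46). Adjusted over the list alone 6 were lower and 2 higher (median −0.09, camera adjusted p = 0.412). Among 9 tumour-initiating cell genes 6 fell, among them the receptor genes PROCR (−1.61) and CD44 (−0.82), and ALDH1A3 (0.87) and BMI1 (0.31) rose, also adjusted over the list alone (median −0.47, camera adjusted p = 0.103). Of 13 angiogenic factor genes 8 fell, including ANGPTL4 (−1.06) and FGF2 (−0.99), whereas THBS1, an inhibitor of angiogenesis, rose from 77.7 ± 3.30 to 197 ± 4.96 TPM (1.33) and EFNA1 rose by 1.11. Angiogenic counts were the same adjusted over the list alone, with a median of −0.29 and a camera adjusted p of 0.199.

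Genes reported elsewhere to respond to GATA3 in breast cells moved in both directions, with 3 higher and 6 lower of 12 tested, also adjusted over the list alone. LY6E, a membrane protein that is itself induced by interferon, fell from 676 ± 26.0 to 42.1 ± 1.91 TPM (−3.98), while TGFB1, LOX and ID3 rose by 0.69, 0.29 and 0.25. The median was −0.10 and the camera adjusted p 0.599. The list holds no reported direction for each gene, so these values cannot tell whether the reported responses were seen. Other GATA factors did not pass: GATA2 was at 37.0 ± 1.79 and 36.5 ± 3.26 TPM and GATA6 at 8.43 ± 0.475 and 8.03 ± 0.388 TPM, with log2 fold changes of −0.02 and −0.06 that took the other sign after quantile normalization. GATA2 also changed sign with median ratio scaling (0.03), without control replicate 1 (0.01) and without GATA3 replicate 2 (0.03). TFAP2A, a factor of the AP-2 family, rose by 0.37 and TFAP2C and TRPS1 fell by 0.53 and 0.51. The cofactor genes ZFPM1 (0.36), ZFPM2 (−0.29) and LMO4 (0.06) did not pass, although ZFPM1 did with median ratio scaling (adjusted p = 0.0457), after quantile normalization (0.0312), without an intensity trend (0.0264) and among protein-coding genes alone (0.0410), within a range of 0.0264 to 0.841. ZFPM2 passed without an intensity trend (adjusted p = 0.0273, range 0.0273 to 1) and LMO4 after quantile normalization (adjusted p = 0.0497, range 0.0497 to 1). Of the 8 tested GATA family and cofactor genes 1 was thus higher and 2 lower (2 and 2 adjusted over the list alone), with a median of −0.04, a mean of −0.08 and a camera statistic pointing upward (adjusted p = 0.845). Only 4 of 16 T helper 2 genes could be tested, too few for a list test. Of these STAT6 fell by 0.47 and NFIL3 by 0.74, IL24 (−0.39) and RUNX3 (−0.11) did not pass, and 3 were lower adjusted over the list alone (median −0.43).

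Of the 31 lists tested, 6 passed with the preset correlation, and with an estimated correlation 1 did, the interferon-stimulated genes.

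Annotation terms carried by the authors' table included antiviral and ribosomal groups. Defense response to virus held 65 lower genes of 110 tested (Fisher's exact test, adjusted p = 1.42e-11) and type I interferon signaling 26 of 35 (adjusted p = 5.51e-07). Genes of ribosome assembly were over-represented among lower genes, with rRNA processing at 64 of 140 (adjusted p = 2.16e-05). Among them NOP56 and UTP4, factors of small-subunit assembly, fell by 0.30 and 0.52 on the log2 scale. tRNA aminoacylation held 21 lower genes of 35 (adjusted p = 0.00198), led by the synthetase genes WARS1 (−1.41) and GARS1 (−0.45). The fall of WARS1 was large for this term, whose median was −0.24. Counted by symbol, 20 of 140 rRNA processing genes and 2 of 35 tRNA aminoacylation genes rose. Among higher genes, the KEGG ribosome term held 61 of 128 (adjusted p = 1.90e-14), with RPLP0 at 0.34 and RPS4X at 0.36. Extracellular matrix organization held 42 higher genes of 111 (adjusted p = 3.21e-06) and muscle contraction 19 of 45 (adjusted p = 0.00264), the latter with MYL9, a myosin light chain gene, from 41.5 to 231 TPM (2.45) and TPM1, tropomyosin, from 79.6 to 225 TPM (1.49). Both terms also held lower genes: counted by symbol, 34 of 106 tested matrix genes and 10 of 43 muscle genes fell, beside 42 and 18 that rose. The matrix term had a median of 0.10 and a mean of −0.01, which became 0.04 with median ratio scaling and 0.06 after quantile normalization. In all 44 of 3804 tests of terms passed, 15 GO and 2 KEGG among higher genes and 18 GO and 9 KEGG among lower genes. A term is counted in each direction in which it passed. Cell adhesion passed in both, with 54 higher and 70 lower genes of 196. Counted by symbol, 58 of 83 tested cytosolic ribosomal protein genes rose and 4 fell (median 0.15), against 41 and 8 after quantile normalization and 64 and 2 with median ratio scaling. Mitochondrial ribosomal protein genes went the other way, 35 of 78 lower and 3 higher (median −0.15). After quantile normalization 28 were lower and 5 higher (median −0.08), and with median ratio scaling 29 and 6 (median −0.10).

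The share of all transcripts held by cytosolic ribosomal protein genes was 16.9 ± 0.443% in control and 19.0 ± 0.0913% in GATA3 cells. Replication-dependent histone genes held 0.0509 ± 0.00108% and 0.0261 ± 0.000982%, and the 50 highest genes held 25.6 ± 0.149% and 27.2 ± 0.339%. Each of these 3 differences had an exact permutation p of 0.1, the smallest possible, and 0.133 after adjustment over 4 shares. Mitochondrially encoded transcripts held 9.27 ± 0.497% and 9.16 ± 0.379% (exact permutation p = 0.9), and this difference changed sign without control replicate 1 (0.171 percentage points) or GATA3 replicate 1 (0.103).

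Markers of other cell types were mostly at low levels. Of 12 immune markers 2 could be tested: CD68, a lysosomal protein gene of macrophages that other cells also express, fell from 36.6 ± 2.80 to 8.47 ± 2.61 TPM (−2.02), and CD14 rose from 0.877 ± 0.367 to 1.87 ± 0.340 TPM (0.63, adjusted p = 0.0354). Summed immune markers were at 37.9 and 10.6 TPM, moving in the direction of the interferon-stimulated genes. None of 10 endothelial and none of 7 erythroid markers could be tested, with sums of 0.243 and 0.337 TPM and of 1.73 and 0.433 TPM. Of 4 tested fibroblast markers COL1A1 (1.86) and COL3A1, from 37.1 ± 2.28 to 86.5 ± 5.33 TPM, rose, while FAP (−0.25) and CFD (0.27) did not pass, and the list summed to 52.6 and 119.6 TPM. Of 5 tested epithelial markers KRT8, KRT14 and KRT18 rose and KRT5 and KRT6A fell, with sums of 985 and 3161 TPM. All counts of these marker lists were the same adjusted over the list alone.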

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

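Shares of summed TPM over protein-coding genes alone were added after the data were seen, and there the mitochondrial share differed by −0.0937 percentage points. The other settings in this part were chosen before their results were seen. GATA3 kept its direction and its side of the threshold in every setting run. The 5155 called genes became 1564 against a change of 1.2-fold and 3176 at a threshold of 0.01, by construction stricter tests. The 689 genes changed at least 2-fold became 307 with a pseudocount of 5 TPM, which shrinks the folds of low genes, and 417 among genes with a mean of at least 5 TPM, where fewer genes were tested. The 44 terms became 117 against a change of 1.2-fold and 78 at a threshold of 0.01, and the cause was not tested. The 6 gene lists became 1 with an estimated correlation, 27 with fry's directional test and 31 with its mixed test, neither of which compares a list with other genes. Without 1 library at a time, called genes numbered 4119 to 4259, those changed at least 2-fold 582 to 667, lists 5 to 8 and terms 46 to 62, with fewer samples in each fit. The difference in the mitochondrial share ranged from −0.304 to 0.171 percentage points, above 0 without control replicate 1 or GATA3 replicate 1. With the replicate number as a block, 4509 genes, 687 genes changed at least 2-fold, 7 lists and 46 terms passed. Libraries with the same number did not deviate together (r = 0.00126, −0.0388 and −0.0675 across genes). No shared effect of the number was thus seen, which does not settle whether samples were handled in pairs. Of 5155 called genes, 4538 were also called with median ratio scaling and 4296 after quantile normalization. Without the filter the cholesterol, immediate early and angiogenic lists also passed (adjusted p = 0.00869, 0.00805 and 0.0347), as did the cholesterol list with the block (0.0468). With the block MUC1 did not pass (0.0711), while XBP1 (0.0447) and TJP1 (0.0133) did. Over 156 named genes, each in the settings in which it was tested, 2991 of 3066 values kept direction and side, 54 no longer passed, 16 passed in addition, 5 uncalled values moved and none reversed a call, and 111 of 145 called genes passed in each setting that tested them, since some genes fell below a filter. Depth is unknown from TPM, so it is unknown how far low genes are limited by counting error.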

Other observations

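Chosen only after the results were seen were the added gene lists, the chromosome values, and the tests of immune cells and of the other cell line; the remaining tests were fixed before the value each one measures was seen.

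Of 10 targets and feedback inhibitors of ERK signalling in an added list 9 fell in GATA3 cells, also adjusted over the list alone, with a median log2 fold change of −1.45 and a camera adjusted p of 2.12e-07 over the 31 fixed and 3 added lists together. With an estimated correlation it did not pass over these 34 lists (adjusted p = 0.0737). The ERK phosphatase gene DUSP4 fell from 60.2 ± 1.00 to 6.80 ± 0.312 TPM (−2.97, SE 0.05, n = 3), and the feedback inhibitor gene SPRY4 fell from 32.7 ± 0.791 to 6.24 ± 1.49 TPM (−2.24). The transcription factor genes ETV5 and ETV4 fell by 1.58 and 1.32, and EPHA4 did not pass (0.04). The list was written after DUSP6, DUSP4 and FOSL1 had been seen to fall, so its camera test partly restates their fall. A hypothesis is lower ERK pathway output in GATA3 cells. The 7 members not looked at before had a median of −1.32 and 6 of them fell, where 0 or higher would have spoken against it. Lower output may thus be one part of the difference between the cultures, but protein activity was not measured here.

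Of 20 contractile genes of smooth muscle in an added list 13 could be tested, of which 10 rose, led by TAGLN, ACTA2 and MYL9, and 1, SMTN, fell (11 and 1 adjusted over the list alone), with a median of 0.48, a mean of 1.03 and a camera adjusted p of 3.83e-08 over the 34 lists (adjusted p = 0.252 with an estimated correlation). The list was written after TAGLN, ACTA2 and MYL9 had been seen to rise, so its camera test partly restates their rise. TPM1 and CALD1, regulators of actin and myosin, rose by 1.49 and 1.08, while CNN1 and MYH11, abundant in differentiated smooth muscle, stayed at means of at most 0.337 TPM. The hypothesis of a joint rise beyond the genes that prompted it stays open. The 10 members taken as not looked at before had a median of 0.37, with 7 higher and 1 lower. That median lay between the bounds of 0 and 0.5 set for it. TPM1 is counted among these members, although it stands beside MYL9 and ACTA2 in the muscle contraction term. It may thus have been seen to rise before the test was set.

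The lower interferon-stimulated genes were weighed first. The scaling of libraries would need the list median to come near 0, and it was −3.11 after quantile normalization. Immune cells in the control cultures would bring immune transcripts, and 12 immune markers summed to 0.495% of the interferon-stimulated transcripts in control cells, most of it CD68 at 36.6 TPM. More interferon transcript in control cells may contribute: 3 interferon genes were at 1 TPM or more there and lower in GATA3 cells. IFNB1 fell from 5.32 ± 0.484 to 3.66 ± 0.474 TPM, IFNE from 2.26 ± 0.246 to 0.967 ± 0.315 TPM and IFNL1 from 4.51 ± 1.04 to 1.31 ± 0.242 TPM (limma adjusted p = 0.0230, 0.0106 and 0.00165). These falls of 0.44, 0.74 and 1.24 on the log2 scale are smaller in size than the list median of −3.12. The bound set was lenient, since it asked for at least 1 such gene while 3167 of all 14077 tested genes were lower. The values also cannot tell whether lower interferon transcript preceded or followed the fall of the interferon-stimulated genes. A difference between the 2 vector cultures other than GATA3 cannot be told apart from GATA3, since each group has 1 genotype label and no separate cultures are named.

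All other genes of the added list of 21 interferon ligands were too low to test; the 3 tested were also lower adjusted over the list alone. Interferon receptor and sensor genes, an added list of 20, did not pass as a list: of 19 tested, 2 rose and 6 fell (2 and 7 adjusted over the list alone), with a median of −0.18 and a camera adjusted p of 0.606 over the 34 lists. The nuclease gene TREX1, the double-stranded RNA receptor gene TLR3 and the DNA sensor gene CGAS fell by 1.63, 1.15 and 0.60, whereas JAK1 and the receptor gene IFNAR2 rose by 0.20 and 0.27. IFNAR1 was at 13.6 ± 0.628 and 15.5 ± 1.76 TPM, which did not pass. The added list does not cover all sensors. DDX58, an RNA sensor gene placed in the interferon-stimulated list, fell from 50.1 to 6.89 TPM (−2.70). The KEGG term for cytosolic DNA sensing held 22 lower genes of 40 tested (Fisher's exact test, adjusted p = 0.0170). These include DDX58 and IRF7 of the interferon-stimulated list, so the term partly restates the fall of that list.

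The number of called genes, 5155 across the genome, was weighed next. Gene copy number that differs by local blocks between the cell populations would shift neighbours together. The largest deviation among 264 blocks of 50 neighbouring genes was 0.247 on the log2 scale, on chromosome X, under the bound of 0.3 set for it. It was also under the largest of 1000 shuffles (0.261). That largest shuffle is an extreme value, so lying under it does not show that the block was unshifted. Gene length and transcript GC content had Spearman correlations of −0.0175 and 0.0865 with the fold change across genes, below the bound of 0.1, with GC known for 97.9% of tested genes. Smaller shifts, local or over whole chromosomes, culture differences and GATA3 itself stay open. Of 10 splits of the 6 libraries, only the real one gave as many called genes, at least 2-fold genes, lists and terms. Its counts were 5155, 689, 6 and 44, against at most 3, 3, 4 and 0 in another split. Every other split mixes libraries of both groups, so the group difference counts as spread there and few called genes follow. These splits thus give no reference free of that difference, and 10 splits are too few for a share under 0.05.

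By chromosome, the median log2 fold change was −0.18 on chromosome 3 (54 genes higher, 277 lower), −0.15 on chromosome 9 (52 higher, 182 lower) and 0.08 on chromosome X (129 higher, 62 lower), against −0.06 over all genes. These 3 lay beyond all 1000 shuffles of the genes (largest deviation 0.0944). All 26 blocks on chromosomes 3 and 9 were below the overall median, against 105 of 238 elsewhere. None of the 9 blocks on chromosome X was below it. This did not single out chromosomes 3 and 9, since all 13 blocks on chromosome 16 and all 4 on chromosome 13 were below the overall median too. Chromosomes 16 and 13 deviated by −0.0723 and −0.0482, within the shuffles, which does not show that they were unshifted. On chromosome 16, 42 genes were higher and 169 lower. With every other gene left out, 1 chromosome, X, still lay beyond the shuffles (0.170 against 0.138), and chromosomes 3 and 9 deviated by −0.117 and −0.0961, within them. With all genes these 2 deviated by −0.131 and −0.0990. The largest shuffled deviation was wider with fewer genes (0.138 against 0.0944), so the subset does not show that their shifts failed to hold. No explanation of these values was tested.

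The growth notes name HCC1806, an epithelial breast cancer line, where the titles name BT549. HCC1806 cells express E-cadherin and other epithelial genes, and the highest value of CDH1, EPCAM, ESRP1 and GRHL2 in any library was 1.73 TPM, for CDH1, which argues against libraries made of such cells. The bound for this test was first set at 1 TPM and was raised to 10 TPM after that value had been seen, so under the first bound the test would have been undecided. VIM, abundant in mesenchymal lines, was at 4522 and 4021 TPM. No other explanation of this conflict of labels was tested.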
